A study of Mus musculus with 5 samples.

How the data were processed

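Poly-T bead selected RNA of 5 samples of SV40 T antigen immortalized mouse embryonic fibroblasts (3 labelled WT and 2 labelled KO for SIRT3) was made into Nextera XT libraries and sequenced on an Illumina NextSeq, per the labels' protocols. The submitters' processing notes name STAR, DESeq2 and the genome build mm10, without versions or roles. The counting program, annotation, strand setting and read filters are not given in the sources used here.

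The deposited table held 23337 genes by symbol, with the columns of a DESeq2 comparison and 2 columns of values for each of the 5 libraries. The signal values are, from the values themselves, read counts divided by a size factor per library by the authors: in each library 100% of values were whole multiples of a step, within a tolerance of 0.1 reads, and their mean over libraries equalled the authors' base mean. The authors also deposited RPKM values per library, a log2 fold change with its standard error, a Wald statistic (the score that divides the first by the second) and p-values with adjusted p-values, per the file headers. The deposited log2 fold changes of low genes are drawn towards 0. The authors' table gives a p-value for 17564 genes and an adjusted one for 15222, and 5773 genes were at 0 in all libraries. In the deposited file 25 symbols had been turned into dates by a spreadsheet, and these rows could not be named.

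Multiplying by the size factor gave totals of 41758681, 37396488, 39909127, 33473103 and 33579031 reads for WT replicates 1, 2 and 3 and KO replicates 1 and 2. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 7.60 for WT replicates 1 and 3 and 5.86 for KO replicates 1 and 2 as means over genes, with medians of 1.02 and 1.66), so each was counted as a separate library. Genes with very many reads raise such a mean. The ribosomal RNA precursor Rn45s was at 399106 normalized read counts in WT replicate 1 and 214583 in WT replicate 3. Reads of WT replicate 2 were not used in count tests, because its step, 0.989, is too near 1 for the check that the values are scaled whole reads.

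Samples were grouped by the titles of their labels. The planned test depended on the unit: edgeR for raw counts, limma for normalized values. As the values are normalized, limma 3.58.1 (R 4.3.3) with a trended prior was run on log2(value + 1) for the 13062 genes with a value of 10 or more in at least 2 of the 5 libraries, with genotype as the one factor. Calls are at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(value + 1) scale, which understates those of low genes. Means and SDs are of the normalized read counts.

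From 42 gene lists written before the data were examined (26 on metabolism, stress and fibroblast state, 16 on other cell types and technical signs), 39 had at least 3 tested members and were tested with camera (two-sided, preset correlation 0.01, adjusted over lists). Of the lists' genes, 13 were matched by an older symbol and 15 had no match, 13 of them mitochondrially encoded. The genes named in the text were fixed by rule: the sirtuins, the 6 largest rises and 6 largest falls among called genes with standard symbols, groups that do not overlap and at least the median level, and up to 3 called members per core list or 2 per side list with the smallest adjusted p. Some members of these lists are left out for length, some results are not reported here, and genes chosen after their values were seen are said to be so. Of the 135 genes considered for naming, 47 overlap another annotated gene, and without a stated strand setting their reads may be shared with it. Sirt3 overlaps Ric8a by 69 bp.

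Positions came from a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 also names, for 23017 genes (2262 by a synonym). Transcript length and GC content came from the longest GENCODE M21 transcript of each gene and were available for 98.7% of the genes tested. The median log2 fold change of each 10 Mb bin was compared with 1000 permutations of gene positions by the largest bin.

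Alternatives were TMM and median-ratio rescaling, no filter or a mean of 50 or more, pseudocounts of 0.5 and 5, each library left out in turn, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered whole reads of 4 libraries, the authors' own comparison, stricter thresholds, an estimated correlation and fry. The RPKM scale, removal of the local shift and removal of a GC and length trend were added after seeing the data. The edgeR run called 4108 genes higher and 3953 lower.

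The test was tried on simulated counts of this comparison, with 12969 genes tested and 200 changed. It recovered 50% of the genes changed 1.2-fold, 88% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold, and 11 of its 174 calls (6.32%) were false. Camera called 0 of 40 lists drawn at random. The simulated genes were drawn independently with a common dispersion of 0.00134, so this does not test lists whose genes vary together. The bin scan called the 1 shifted bin of 217 and none without a shift.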

Results

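Messenger RNA was sequenced from mouse embryonic fibroblasts immortalized with the SV40 T antigen, a viral protein that binds and inactivates p53 and the retinoblastoma protein. Of the 5 libraries, 3 were labelled wild type (WT) for SIRT3 and 2 were labelled SIRT3 knockout (KO), all of strain 129Sv and grown under normal conditions. SIRT3 is a deacetylase of the mitochondrial matrix. The title of the study names de novo nucleotide synthesis as a weakness of cells that lack SIRT3, found in a small molecule screen, and the sequencing compared the transcripts of the lines. The values were read counts per gene divided by a size factor per library, called normalized read counts below. The reads recovered from these values came to 41758681, 37396488 and 39909127 in WT replicates 1, 2 and 3 and to 33473103 and 33579031 in KO replicates 1 and 2. The ribosomal RNA precursor Rn45s took 1.08% of the normalized counts in WT replicate 1 and between 0.581% and 0.701% in the other 4 libraries. No label says that the libraries of a genotype came from separate cultures or lines, so the p-values measure the spread between these libraries, which may be technical.

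Sirt3, the targeted gene, was detected in all 5 libraries and was higher in the libraries labelled KO. It lies on chromosome 7 from 140863663 to 140882309 (mm10). Its normalized read counts were 169.7, 149.4 and 118.4 in WT replicates 1, 2 and 3 and 200.4 and 216.8 in KO replicates 1 and 2. The group means were 145.8 ± 25.8 (SD, n = 3) and 208.6 ± 11.6 (SD, n = 2), a log2 fold change of 0.53 with a standard error of 0.152 (limma, adjusted p = 0.0044). The values are totals per gene and do not separate exons, so they cannot show whether a deleted part of the gene is missing from the transcript. The Sirt3 level thus goes against the label KO if the allele gives no transcript, and every direction below is given between libraries as labelled. Of the other sirtuins, Sirt1, a nuclear deacetylase, was 1.11-fold higher in the libraries labelled KO (adjusted p = 0.022), while Sirt2, Sirt6 and Sirt7 were lower, with log2 fold changes of -0.21, -0.45 and -0.51. The mitochondrial family members Sirt4 and Sirt5 did not pass the test, at log2 fold changes of -0.0023 and 0.093. The Sirt1 call was lost without WT replicate 1 (limma, adjusted p = 0.113), without WT replicate 3 (0.0787) and without KO replicate 1, which leaves 1 library labelled KO. It was absent in the authors' deposited table (0.05004), with no filter (0.0721) and on RPKM values (0.0901). With the local shift described below removed, the Sirt1 call held, at a log2 fold change of 0.29 (adjusted p = 9.5e-05). The Sirt3 call was lost with DESeq2 on the recovered reads of 4 libraries (log2 fold change 0.53, adjusted p = 0.0631). It was also lost with the local shift removed (limma, adjusted p = 0.255). It held with edgeR on the same 4 libraries (adjusted p = 0.0116) and in the authors' deposited comparison (log2 fold change 0.48, adjusted p = 0.0190).

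**Figure D1:**
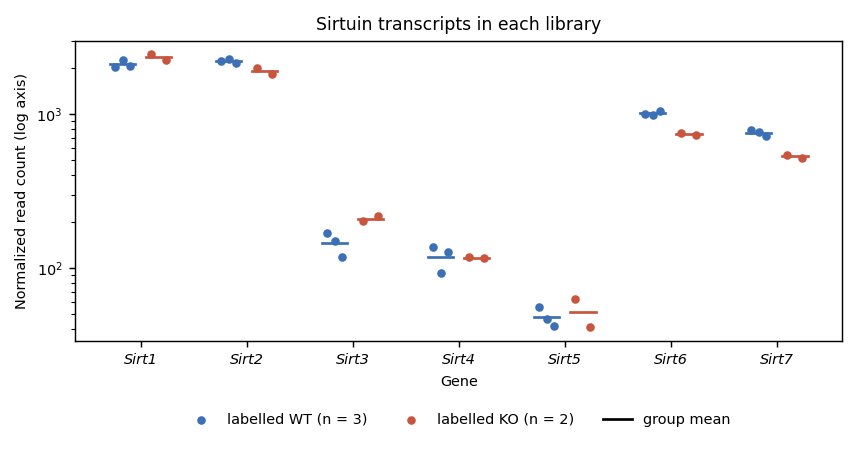
Normalized read counts (log axis) of the 7 sirtuin genes, with a point for each library labelled WT (n = 3) or KO (n = 2) and a bar at each group mean. Both Sirt3 values of the libraries labelled KO, 200.4 and 216.8, lie above the highest of the libraries labelled WT, 169.7.

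Among 13062 genes tested, 4259 were higher and 4264 lower in the libraries labelled KO at an adjusted p under 0.05 (limma). Most of these differences were small: the median size of a called log2 fold change was 0.44, and 858 higher and 837 lower genes differed at least 2-fold. The groups did not overlap for 75.4% of the genes tested, where chance gives 20%. The first principal component held 88.1% of the variance, and the median coefficient of variation within a group was 3.31% for WT and 3.82% for KO. The authors' deposited table called 3912 genes higher and 3774 lower, of which 3848 and 3746 were called in the same direction here and 0 in the opposite one.

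The largest rises among genes of at least median level were those of Fhl1, a LIM domain protein of muscle, and Kcnq1ot1, an imprinted noncoding RNA. Fhl1 (chromosome X, 56731209 to 56793346) went from 890.2 ± 29.9 (SD, n = 3) to 12601 ± 247 (SD, n = 2) normalized read counts in the libraries labelled KO, a 14.1-fold difference. Kcnq1ot1 was 13.9-fold higher, and lies for its whole 83437 bp inside Kcnq1. The strand setting of the counting is not stated, so its reads cannot be told apart from those of Kcnq1. Kcnq1 itself was not among the genes tested. Other large rises were those of the cyclin D2 gene Ccnd2 (8.75-fold), the intermediate filament gene Nes (6.53-fold) and the RNA-binding protein gene Celf2 (6.41-fold). The largest fall was that of Stmn2, a neuronal regulator of microtubules (chromosome 3, 8509527 to 8561604), which went from 4438 ± 85.9 to 18.3 ± 0.908 and was thus 231-fold higher in the libraries labelled WT. The vasopressin receptor gene Avpr1a was 99.6-fold, the repressor gene Bcl6b 50.4-fold, Igfbp3, which binds insulin-like growth factors, 37.5-fold, the transcription factor gene Sim2 29.7-fold and the ectodysplasin receptor gene Eda2r 20.9-fold higher in WT. Each of these 11 genes had an adjusted p of 1.3e-17 or less (limma).

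**Figure D2:**
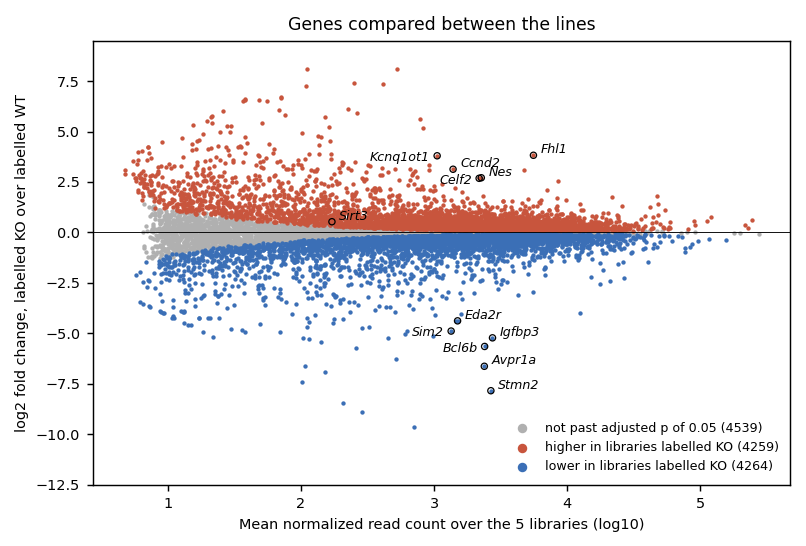
Log2 fold change of the libraries labelled KO over those labelled WT (vertical axis) against the mean normalized read count over the 5 libraries (log10, horizontal axis), with a point for each of the 13062 genes tested. The 4259 higher and 4264 lower genes lie at all levels, and the circled genes are Sirt3 and the 11 genes named for large changes at or above the median level.

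De novo purine synthesis, the route that builds IMP and from it AMP and GMP, was higher as a group: of 13 genes measured, 10 rose and 1 fell, with a median log2 fold change of 0.22 (camera, adjusted p = 0.0293). With an estimated correlation between genes in place of the preset 0.01, the adjusted p was 0.365. The estimate itself was -0.062, so this loss does not come from a correlation above the preset. Impdh1 (chromosome 6, 29200436 to 29216364), for the committed step to GMP, rose from 2298 ± 55.7 (SD, n = 3) to 3703 ± 50.5 (SD, n = 2), a log2 fold change of 0.69. Paics (chromosome 5, 76951302 to 76967509), a bifunctional enzyme of the middle of the route, rose by 0.36, and Prps2, for the precursor PRPP, by 0.50 on the log2 scale. Adss, which acts on the way to AMP, fell, with a log2 fold change of -0.25. The list's call was lost without WT replicate 3 (adjusted p = 0.0502).

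De novo pyrimidine and dNTP synthesis did not differ from other genes as a group (13 genes, 6 higher, 3 lower, camera adjusted p = 0.456). Rrm2, a subunit of ribonucleotide reductase, rose by 0.35 and Cad, for the first steps of pyrimidine synthesis, by 0.26 on the log2 scale. Among the genes that fell were Dtymk and Tyms, both on the route to dTTP, at -0.36 and -0.12. Nucleotide salvage missed the threshold (21 genes, 13 higher, 3 lower, adjusted p = 0.094). In it Aprt, which recovers adenine, was 2.48-fold and the nucleoside transporter gene Slc29a1 1.45-fold higher in the libraries labelled KO, and the uridine phosphorylase gene Upp1 was 2.38-fold higher in WT. Aprt lies in the segment of chromosome 8 described below, whose genes had a median log2 fold change of 1.01.

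Serine and one-carbon metabolism, which supplies carbon units to purines and thymidylate, was higher in the libraries labelled KO (16 genes, 11 higher, 2 lower, median 0.27, camera adjusted p = 0.0092, and adjusted p = 0.348 with an estimated correlation). The mitochondrial enzyme genes Mthfd2 and Aldh1l2 were 1.86-fold and 3.59-fold higher and Psat1, of serine synthesis, was 1.44-fold higher. Glutamine and aspartate metabolism did not pass as a group (23 genes, 13 higher, 6 lower, adjusted p = 0.0922). Its glutamate and aspartate transporter gene Slc1a3 was 7.78-fold higher in WT, from 8497 ± 121 to 1091 ± 33.2, while the transporter gene Slc7a5 and the aspartate aminotransferase gene Got1 were 2.65-fold and 2.52-fold higher in the libraries labelled KO. Neither the pentose phosphate pathway (8 genes, 6 higher, 1 lower, adjusted p = 0.0932) nor glycolysis (23 genes, 13 higher, 5 lower, adjusted p = 0.0932) passed. Gapdh, Aldoa and Pgam1 were 1.45-fold, 1.53-fold and 1.55-fold higher, and Tkt, of the pentose phosphate pathway, 1.29-fold.

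None of the mitochondrial lists passed in the fit of all 5 libraries. Nuclear genes of oxidative phosphorylation gave 32 higher and 11 lower of 72 (median 0.10, camera adjusted p = 0.0922), the tricarboxylic acid cycle 8 and 6 of 24 (0.675), fatty acid oxidation 10 and 3 of 22 (0.196) and the mitochondrial unfolded protein response 7 and 1 of 13 (0.0615). Other settings moved 2 of them both ways. The outcome for oxidative phosphorylation depended on which library labelled KO was kept: the list passed without KO replicate 2 but not without KO replicate 1. The mitochondrial unfolded protein response also passed without KO replicate 2. Each of these fits leaves 1 library labelled KO. Oxidative phosphorylation passed with the local shift described below removed (camera adjusted p = 0.0473). With a GC and length trend removed it was at 0.456 (median 0.060). The mitochondrial unfolded protein response passed with no filter (0.0345) and was at 0.354 (median 0.064) with the local shift removed. The cytochrome oxidase gene Cox4i1 rose by 1.10 and the complex I gene Ndufb8 by 0.96 on the log2 scale. Hspd1 and Hspe1, the mitochondrial chaperonin pair, were 1.36-fold and 1.46-fold higher, and the dienoyl-CoA reductase gene Decr1 was 3.58-fold higher. Antioxidant genes and NRF2 targets split, with 10 higher and 14 lower of 28 (adjusted p = 0.254). Nfe2l2, which encodes NRF2, and its target Nqo1 were 2.05-fold and 2.92-fold higher in WT, whereas the glutathione reductase gene Gsr was 1.76-fold higher in the libraries labelled KO. Hypoxia-inducible genes gave 6 higher and 9 lower of 20 (adjusted p = 0.642), with Pdk1 2.31-fold and Ndrg1 2.04-fold higher in WT. The integrated stress response gave 11 higher and 9 lower of 22 (adjusted p = 0.701), among them Asns at 1.28 and Atf5 at -1.13. Mitochondrially encoded genes were not analysed here.

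Cholesterol synthesis rose in the libraries labelled KO, with 21 genes higher and 2 lower of 24 and a median log2 fold change of 0.51 (camera, adjusted p = 1.9e-08, and adjusted p = 0.348 with an estimated correlation). Sc4mol, a sterol demethylation enzyme gene, went from 3509 ± 74.5 (SD, n = 3) to 10093 ± 520 (SD, n = 2), and Mvd, of the mevalonate pathway, was 3.43-fold higher. Fatty acid synthesis missed the threshold (15 genes, 9 higher, 3 lower, adjusted p = 0.0553), with the desaturase genes Scd2 and Fads2 3.53-fold and 1.95-fold and the elongase gene Elovl6 1.91-fold higher. The list passed without WT replicate 3 (0.0398), KO replicate 1 (0.0177) or KO replicate 2 (0.0329), and with other settings given among the processing alternatives. MYC and ribosome biogenesis genes were higher too (24 genes, 16 higher, 3 lower, median 0.26, adjusted p = 0.0019, and adjusted p = 0.348 with an estimated correlation), led by Nolc1, Rrp12 and Nop2 at 0.73, 0.67 and 0.62. Cytosolic ribosomal proteins gave 57 higher and 3 lower of 74 (median 0.27, adjusted p = 1.3e-08, and adjusted p = 0.511 with an estimated correlation), with Rpl13 2.33-fold higher. Ribosomal protein genes and Gapdh have many near-identical pseudogenes, and their values are uncertain where the counting could split reads. DNA replication and cell cycle genes did not pass (32 genes, 16 higher, 7 lower, camera adjusted p = 0.113), nor did replication-dependent histones (6 genes, 0 higher, 2 lower, adjusted p = 0.771). Only these 6 of the 21 histones listed were tested in this poly-T selected RNA, so that list says little about the cell cycle. Mki67, a proliferation marker, rose by 0.46 on the log2 scale.

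Interferon-stimulated genes were lower in the libraries labelled KO in 28 of 29 cases, with a median log2 fold change of -1.89 (camera, adjusted p = 8.9e-09, and adjusted p = 0.303 with an estimated correlation). Oasl2 went from 187.8 ± 4.03 (SD, n = 3) to 3.87 ± 0.756 (SD, n = 2) normalized read counts. Ddx58, which encodes the RNA sensor RIG-I, was 3.72-fold and Xaf1 19.4-fold higher in WT. Ifit2 alone rose, by 1.14 on the log2 scale, and lies in the chromosome 19 block described below (0.58 with the local shift removed). Inflammatory cytokines and chemokines gave 3 higher and 15 lower of 19 (median -0.74, adjusted p = 0.0034, and adjusted p = 0.365 with an estimated correlation). The chemokine gene Ccl2 was 3.59-fold and Mmp3, a matrix protease gene on the same list, 4.07-fold higher in WT, and the 3 genes that rose were Cxcl12, a chemokine gene, Icam1, for an adhesion molecule, and Tnfaip3, for an inhibitor of NF-kB signalling. Targets of p53 missed the threshold (20 genes, 3 higher, 11 lower, adjusted p = 0.0553), with Cdkn1a 1.90-fold higher in WT and Plk2 1.89-fold higher in the libraries labelled KO. The p53 list passed without WT replicate 2 (adjusted p = 0.0387) or KO replicate 1 (0.0392).

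Contractile and TGF-beta genes were higher in the libraries labelled KO, with 11 higher and 3 lower of 17 and a median of 0.84 (camera, adjusted p = 0.0044, and adjusted p = 0.365 with an estimated correlation). Tagln, an actin-binding protein gene of smooth muscle, was 4.32-fold and Ctgf 3.38-fold higher. Tgfbi, Tgfb1 and Skil fell, at -2.35, -0.94 and -0.31. Fibroblast matrix genes split, with 9 higher and 12 lower of 26 (adjusted p = 0.211). Pdgfra, the receptor gene often used to mark fibroblasts, went from 20013 ± 229 (SD, n = 3) to 1255 ± 98.6 (SD, n = 2), and Thbs2 and Col3a1 were 5.35-fold and 4.75-fold higher in WT. Lysosome and autophagy genes gave 11 higher and 13 lower of 27 (adjusted p = 0.523), with the lysosomal genes Hexa and Npc2 2.17-fold and 1.82-fold higher in WT. Markers of other cell types did not pass as lists, for epithelium (5 genes, adjusted p = 0.472), endothelium (8 genes, 0.555), muscle (4 genes, 0.782), cartilage and bone (9 genes, 0.782), neurons and glia (13 genes, 0.908), macrophages and blood (3 genes, 0.952) and adipocytes (5 genes, 0.977). Single members differed in both directions: Spint1, Flt1, Tnnt2 and Spp1 were 3.00-fold, 2.78-fold, 3.49-fold and 3.28-fold higher in the libraries labelled KO, and Dsp, Egfl7 and Col11a1 were 2.13-fold, 2.10-fold and 2.45-fold higher in WT. Immediate early and heat shock genes gave 9 higher and 6 lower of 22 (adjusted p = 0.719), with Egr3 3.34-fold higher in WT and Hsph1 1.46-fold higher in the libraries labelled KO.

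**Figure D3:**
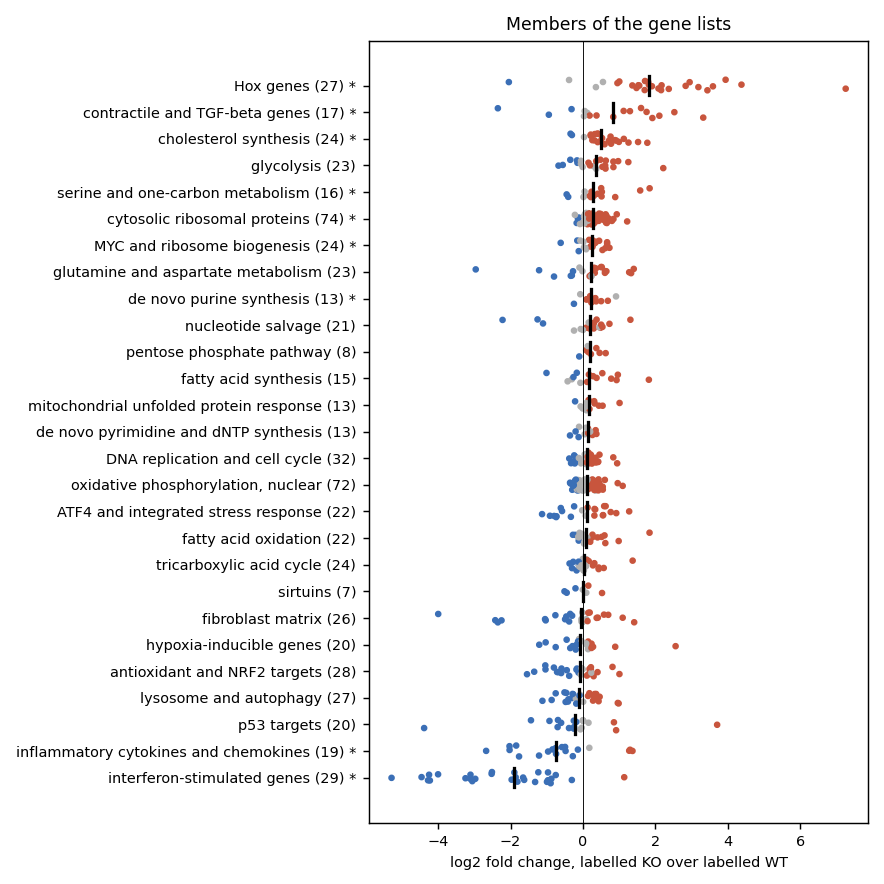
Log2 fold change of the libraries labelled KO over those labelled WT (horizontal axis) for each tested member of 27 gene lists, with the number of members in brackets, red for higher, blue for lower and grey for not past an adjusted p of 0.05. Black bars are list medians, from -1.89 for interferon-stimulated genes to 1.82 for Hox genes, and an asterisk marks a camera adjusted p under 0.05.

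Members of the called lists that went against their group are named here after their values were seen, as were Ifit2, Icam1, Tnfaip3, Tgfb1, Skil, Adss and Tyms. In cholesterol synthesis they were Ebp (-0.30) and Tm7sf2 (-0.34), in serine and one-carbon metabolism Mtr (-0.41) and Amt (-0.45), among MYC and ribosome biogenesis genes Odc1 (-0.61), Utp20 (-0.16) and Fbl (-0.12), and among ribosomal proteins Rpl28 (-0.17), Rpl19 (-0.14) and Rps15 (-0.11), as log2 fold changes. Leaving out single libraries ended 4 of these calls. The adjusted p of Tm7sf2 was 0.237 without WT replicate 3 and 0.212 without KO replicate 1, and that of Amt was 0.0937, 0.188 and 0.209 without WT replicate 1, WT replicate 3 and KO replicate 1. For Fbl it was 0.1001, 0.0519 and 0.0910 without the same 3 libraries, and for Rps15 it was 0.0742, 0.0633 and 0.138 without WT replicate 1, WT replicate 3 and KO replicate 2. In the authors' deposited table the adjusted p was 0.126 for Tm7sf2, 0.124 for Amt and 0.0503 for Fbl, and DESeq2 on 4 libraries gave 0.150, 0.104 and 0.0921 for these and 0.133 and 0.0936 for Icam1 and Tyms. With no filter Tm7sf2 and Amt were at 0.0964 and 0.0987, and on RPKM values Rps15 was at 0.0587. With the local shift described below removed, Amt was not called (0.123), and 5 of these genes had log2 fold changes above 0: Utp20 (0.13, adjusted p = 0.0099), Rpl19 (0.15, 0.0038), Rps15 (0.17, 0.0018), Fbl (0.020, 0.703) and Rpl28 (0.026, 0.591). That setting left 69 ribosomal proteins higher and 0 lower. Of the 39 lists tested, 10 were called with the preset correlation and 0 with an estimated one (5 at an unadjusted p under 0.05). An estimate under the preset 0.01 did not keep a call, as for interferon-stimulated genes (0.0094). Fry called 32 lists, and asks whether the genes of a list move one way and not whether they differ from other genes. The median, mean and test differed in sign for the neuron and glia, cartilage and bone, macrophage and blood, adipocyte and other patterning lists, none of them called. Counts adjusted over the list alone were equal to those over all genes for 33 of the 39 lists. For the others, the counts adjusted over the list alone were 15 higher and 6 lower for glutamine and aspartate metabolism, 31 and 11 for oxidative phosphorylation, 7 and 1 for the pentose phosphate pathway, 11 and 14 for antioxidant genes, 60 and 3 for ribosomal proteins and 22 and 6 for the genes next to Sirt3.

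Genes that lie together on a chromosome differed together. Of 217 bins of 10 Mb with at least 20 tested genes, 20 had a median log2 fold change beyond that of permuted gene positions, 18 higher and 2 lower in the libraries labelled KO, in 12 blocks (permutation test over 1000 permutations, p adjusted by the largest bin). The largest shift was on chromosome 8 from 120 to 130 Mb, with a median of 1.01 over 82 genes and 97.6% of them above 0, against a largest permuted bin median of 0.546. Chromosome 8 from 0 to 50 Mb and from 60 to 80 Mb had medians of 0.54 and 0.50, and chromosome 19 from 10 to 50 Mb had 0.45 over 237 genes. Further blocks above 0 lay on chromosomes 6, 7 and 17, and those below 0 were chromosome 10 from 120 to 130 Mb (-0.39) and chromosome 11 from 100 to 110 Mb (-0.42). The shifts reached beyond these blocks, which hold only the bins past the threshold. Over all tested genes of a chromosome, the median was 0.41 for 8, 0.32 for 6, 0.32 for 19 and 0.30 for 17. Other chromosomes lay between -0.21 (chromosome 10) and 0.075 (chromosome 18). Every tested bin of chromosomes 6 and 8 had a median above 0, while 17 and 19 each also held a bin below 0. Between pairs of libraries of a group, the largest bin median was 0.102.

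Some of the genes named above lie in these blocks. In the chromosome 8 segment from 120 to 130 Mb are Aprt, Mvd, Slc7a5, Cox4i1, Rpl13, the replication genes Cdt1 and Gins2, Spg7, a mitochondrial protease gene, Map1lc3b, of autophagy, and Egln1, an oxygen sensor gene. When the local shift of the 25 nearest genes on each side was subtracted, a setting chosen after seeing the data, the log2 fold change went from 1.31 to 0.33 for Aprt, from 1.78 to 0.81 for Mvd, from 1.40 to 0.45 for Slc7a5, from 1.10 to 0.21 for Cox4i1 and from 1.22 to 0.21 for Rpl13. Spg7 and Map1lc3b went from 1.01 and 0.96 to 0.00058 and 0.0057 and lost their calls, as did Cdt1 and Gins2, from 0.95 and 0.84 to -0.047 and -0.012. Egln1 went from 0.89 to -0.13. In the other blocks, Impdh1 went from 0.69 to 0.36, Psat1 from 0.52 to 0.13, Sc4mol from 1.52 to 0.97, Got1 from 1.33 to 0.72, Nolc1 and Rrp12 from 0.73 and 0.67 to 0.22 and 0.20, and Gsr from 0.82 to 0.27. Ndufb8 went from 0.96 to 0.39, Scd2 from 1.82 to 1.28, Fads2 from 0.96 to 0.57 and Pgam1 from 0.63 to 0.15. Mki67 lost its call (0.080, adjusted p = 0.132). Of the 15 fatty acid synthesis genes tested, 5 lie in called blocks. Genes outside the called blocks moved too: Mthfd2 from 0.89 to 0.58, Nop2 from 0.62 to 0.37, Gapdh and Aldoa from 0.54 and 0.61 to 0.29 and 0.27, Slc29a1 from 0.54 to 0.21, Dtymk from -0.36 to -0.19 and Sirt6 from -0.45 to -0.18, and Sirt7 lost its call (-0.17, adjusted p = 0.0562). Paics, also outside, was at 0.34 after 0.36.

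**Figure D4:**
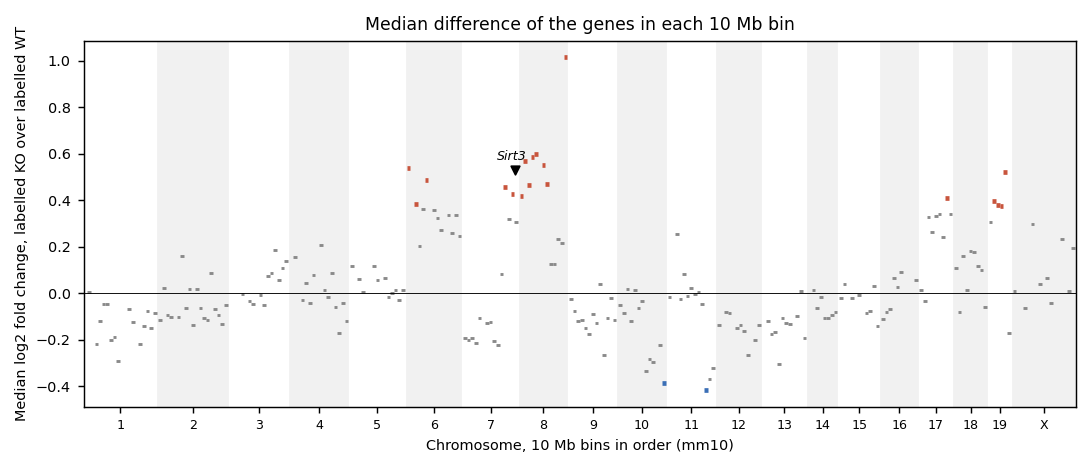
Median log2 fold change of the libraries labelled KO over those labelled WT (vertical axis) of the tested genes in each 10 Mb bin, in order along chromosomes 1 to 19 and X (horizontal axis, mm10). The 20 bins past the permutation test are red (18, higher) or blue (2, lower), other bins are grey, and the triangle marks Sirt3 at its own log2 fold change of 0.53.

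The genes around Sirt3 shared its direction. Of 116 other tested genes within 10 Mb of it, 90 (77.6%) had a log2 fold change above 0, and their median was 0.31, beyond the medians of 10000 random sets of as many genes (permutation test, p = 0.0001, the smallest that 10000 draws can give). This p was computed after the values were seen and is not adjusted for the other regions. In the scan adjusted by the largest bin, the bin that holds Sirt3, 140 to 150 Mb, had a median of 0.31 and was not called (permutation p = 0.24), while the bin before it, 130 to 140 Mb, was called (p = 0.014). Sirt3 stood at the 75.9th percentile of these neighbours. With the local shift removed, which subtracts the values of its nearest neighbours, its log2 fold change was 0.20 with a standard error of 0.151 (adjusted p = 0.255), against 0.53 with 0.152 before. The list of genes next to Sirt3 fixed before the data were examined gave 21 higher and 6 lower of 34 (median 0.30, camera adjusted p = 0.0477, and adjusted p = 0.365 with an estimated correlation). This call was lost without WT replicate 2 (adjusted p = 0.056), WT replicate 3 (0.0502) or KO replicate 2 (0.0685) and with a pseudocount of 5 (0.052). Removal of the local shift does not test this list, since it subtracts the values of largely the same genes. Its strongest members were Irf7 and Ifitm3, both interferon-inducible and 9.47-fold and 2.36-fold higher in WT, and Irf7 is also on the list of interferon-stimulated genes.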

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

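The RPKM scale, the local shift and the GC and length trend were chosen after seeing the data. Across normalizations, filters, pseudocounts, tests and the stricter p, 3376 to 4360 genes were higher and 3328 to 4470 lower, all within 1.5 times the reported counts, and requiring 2-fold left 858 and 837. Leaving out a library gave 3767 to 4026 higher and 3870 to 4128 lower genes, 9 to 13 called lists and a Sirt3 log2 fold change of 0.387 to 0.645. The Sirt3 call was lost with DESeq2 (0.530, adjusted p = 0.0631, on 4 libraries) and with the local shift removed (0.204, adjusted p = 0.255). Its adjusted p ranged from 0.0031 to 0.255 over all settings. Called lists went from 10 to 0 with an estimated correlation and to 32 with fry, which asks another question. The estimated form asks the same question as the main test, but with degrees of freedom limited by the 5 libraries. Its estimates were under the preset 0.01 for interferon-stimulated genes (0.0094), serine and one-carbon metabolism (-0.0043) and de novo purine synthesis (-0.062). Those calls were thus lost without a higher correlation. For the other called lists the estimate was above 0.01, up to 0.497 for ribosomal proteins. Some lists passed only under an alternative other than fry, given here apart from single libraries left out and the replicate block described below. With no filter they were fatty acid synthesis (adjusted p = 0.0431), the mitochondrial unfolded protein response (0.0345), nucleotide salvage (0.0421), p53 targets (0.0244) and the pentose phosphate pathway (0.0494). With the local shift removed they were fatty acid synthesis (0.00755), oxidative phosphorylation (0.0473) and lysosome and autophagy genes (0.0421). With the GC and length trend removed they were fatty acid synthesis (0.0377) and p53 targets (0.0433). For 135 genes, 2351 of 2425 values kept direction and side of the threshold, 57 lost the call and 17 changed sign. Sirt4 and Sirt5, never called, changed sign without single libraries, over ranges of -0.170 to 0.110 and of -0.205 to 0.392, and Sirt4 also with TMM (7.34e-05). With the local shift removed, Cdt1 (-0.0467), Gins2 (-0.0125), Acsl1 (-0.00612), Egln1 (-0.132), Fbl (0.0203), Utp20 (0.130), Rpl19 (0.155), Rpl28 (0.0260) and Rps15 (0.167) changed sign, as that setting subtracts the values of neighbours. The rescalings moved the median of all genes from -0.0023 to no further than 7.6e-05.

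The replicate numbers did not pair the libraries: deviations from the group means of the libraries with the same number correlated at -0.0093 and 0.027 across genes. With the replicate block, 3958 genes were higher and 3947 lower, Sirt3 was at 0.387 (adjusted p = 0.0301), 11 lists were called, Sirt4 was at 0.0535 and Sirt5 at -0.00119. De novo purine synthesis (adjusted p = 0.154) and the genes next to Sirt3 (0.222) were not called under the block, and fatty acid synthesis (0.0064), p53 targets (0.0222) and fibroblast matrix (0.0004) were.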

Other observations

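The tests of the Sirt3 pattern were chosen only after the result was seen, and the genes Hoxc10, Xist and Prdm1 were named after their values were seen.

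Hox genes, which record the position of a cell along the body, gave 23 higher and 1 lower of 27 in the libraries labelled KO (median log2 fold change 1.82, camera adjusted p = 8.0e-05, and adjusted p = 0.348 with an estimated correlation). Of these 27 genes, 8 lie in the called chromosome blocks, so the Hox result and the blocks are not separate. The list's median was 1.74 with the local shift removed. Hoxb9 went from 130.7 ± 10.6 (SD, n = 3) to 591.6 ± 20.5 (SD, n = 2) normalized read counts, Hoxd13 from 0.898 ± 0.884 to 270.3 ± 66.2, and Hoxc10 was the 1 that fell, 4.13-fold higher in WT. Other patterning factors gave 14 higher and 21 lower of 39 (adjusted p = 0.311, but 0.0392 without KO replicate 1 and 0.0248 without KO replicate 2), with Lhx8 2.63-fold higher in WT. Imprinted genes gave 10 higher and 5 lower of 21 (adjusted p = 0.272): Rian, a noncoding RNA expressed from the maternal allele, was 6.15-fold higher in the libraries labelled KO and Grb10 1.84-fold higher in WT.

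Xist, the RNA that coats the inactive X chromosome, was at 99494 ± 4963 (SD, n = 3) in the libraries labelled WT and 60508 ± 5021 (SD, n = 2) in those labelled KO, a log2 fold change of -0.72 (limma, adjusted p = 4.6e-11). The Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 reads in all 5 libraries, which allows up to 3 reads in each, and Uty was at 1.85 in WT replicate 3, 2.20 in KO replicate 1 and 0 in the others. Of the pluripotency and germ cell markers only 2 were tested, among them Prdm1, 8.90-fold higher in WT.

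Sirt3 was higher in the libraries labelled KO. Whether it took part in a shift of distal chromosome 7 stays open: its place at the 75.862th percentile of 116 genes within 10 Mb decides nothing, since the range that holds most of these genes, -1.04 to 1.31, also held 89.0% of all tested genes. The 10 Mb bin that holds Sirt3 was not called in the adjusted scan (permutation p = 0.24). From 110 to 150 Mb of chromosome 7, the bin medians were 0.46, 0.32, 0.43 and 0.31. Each was above 0 in 6 of 6 pairs of a library labelled KO and one labelled WT. Tested bins from 0 to 100 Mb had medians of -0.22 to -0.11. These values describe the region and do not decide for Sirt3 itself. Whether labels were exchanged between the lines stays open. The lowest count with recovered reads among the libraries labelled WT was 128 reads, which argues against exchange only if the knockout allele gives none. If that allele gives none, the Sirt3 reads in every library go against a knockout in either line. Exchanged labels would thus also need an allele that still gives transcript. A biological rise of Sirt3 transcript from the targeted allele was not tested, since the table does not separate exons.

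Neighbouring genes differed together in blocks along chromosomes. GC content and length of the longest annotated transcript did not account for the largest block, whose median went from 1.0145 to 1.0363 when their trend was removed. Variation between single libraries did not either, since the largest bin median within a group was 0.10214. Differences in DNA copy number between the lines stay open, as no DNA measurement was analysed here, and the lowest share of genes above 0 among 3 expression classes of the largest block (96.296%) decides nothing, since with 2 of its 82 genes not above 0 no class could fall under 92.6%. An effect of the SIRT3 genotype on these segments stays open and untested.

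De novo purine synthesis, cholesterol synthesis and cytosolic ribosomal proteins were higher as lists in the libraries labelled KO (camera, adjusted p of 0.0293, 1.9e-08 and 1.3e-08). None of the 3 passed with an estimated correlation between genes (adjusted p of 0.365, 0.348 and 0.511). The estimates were -0.062, 0.061 and 0.497, against the preset 0.01. For the purine list this loss thus does not come from a higher correlation. The purine call was also lost without WT replicate 3 (adjusted p = 0.0502). Position did not account for de novo purine synthesis, whose median went from 0.22 to 0.26018 once the local shift was removed, nor for cholesterol synthesis, which went from 0.51 to 0.58874. With the trend on transcript length and GC content removed, the ribosomal protein median went from 0.27 to 0.17535, so these may account for part of the difference. Whether they account for most of it stays open. They were taken from the longest annotated transcript of a gene, which need not be the one sequenced. An effect of the loss of SIRT3 and a difference between the lines unrelated to SIRT3 stay open, since the labels do not say how many lines stand behind each genotype.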
